A study of Aedes albopictus with 4 samples.

How the data were processed

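Gene expression was measured by RNA sequencing in whole larvae, in the fourth instar, of Aedes albopictus, the Asian tiger mosquito, at 72 h. The 4 libraries formed 2 groups, with 2 libraries from larvae exposed to diquat at 1/5 of the LC50 (the median lethal concentration) and 2 from untreated controls. Per the labels' protocols, RNA was extracted with a Zymo Direct-zol kit and libraries were made with the NEBNext Ultra II RNA kit for Illumina. The submitters' processing notes name fastp 0.12.4, DRAGEN, bcl2fastq and STAR 2.7.10a with no role or order. The read counter, the genome build, the annotation, the strand setting and the normalizing tool are not given in the sources used here.

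The deposited table holds 25320 genes with a normalized signal per library, per the file headers, and 13 columns of annotation including product names. The values of each library were whole multiples of its smallest value above 0 (100% of values whole in each library, at a tolerance of 1e-06 relative to the multiple), so that the authors' values are read counts divided by 1 factor per library. Division by that step gave back whole reads: 34502559 and 39242657 in the control libraries and 45243090 and 48383964 in the diquat libraries. Depth therefore differed between the groups, and the number of reads behind each value sets its counting error. Product names were taken from the table after removal of isoform suffixes, and 13819 genes had no informative name. A few products withheld from this work were treated as undescribed and are not reported here.

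All 25320 gene identifiers were found in the reference table of the AalbF5 assembly. Because no source names the authors' build, that table was used only to find which genes overlap or neighbour each other and how long their genomic spans are. Of 1751 nested gene pairs whose inner gene had a mean of at least 100 normalized counts, the outer gene was at or above the inner gene in all 4 libraries in 1751. Values thus had the form of counts over whole gene bodies, given to every gene that overlaps a read. Of 17992 tested genes, 6779 overlapped another gene, 3355 lay inside another gene, and 571 held a nested gene with 20% or more of their own value. How the authors' counting divided reads among similar gene copies is not given in the sources used here.

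The comparison was diquat against control. Genes with a mean of at least 10 normalized counts over the 4 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean trend) on log2(value + 1), two-sided, with Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. Standard errors (SE) of fold changes are the moderated ones of limma. Each gene's variance was drawn toward the mean trend over all tested genes, so they do not rest on that gene's values alone. The 29 gene lists were defined by product-name patterns and tested with camera at a preset correlation of 0.01, adjusted over the lists. The design, the lists and the rule for named genes were fixed beforehand. The rule took, among genes with a described product, an adjusted p under 0.05, a mean of at least 50 and both diquat libraries on the same side of both controls, the 12 largest positive and 12 largest negative fold changes. Undescribed genes that would have ranked among them were counted and at most 2 per direction named. In each list it took up to 4 members of smallest p with a mean of at least 50. An added list of the 13 proteins encoded by the mitochondrial genome and the search over product-name families were chosen after the data were seen.

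Alternatives set before the data were examined were pseudocounts of 0.5 and 5, other filters on low values, median-ratio, equal-total and quantile scaling, a constant variance prior, the replicate number as a block, each library left out, a 2-fold minimum, camera with an estimated correlation, fry, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. Alternatives chosen after seeing the data kept only genes on a chromosome and without overlap, kept only nuclear protein-coding genes, or removed each library's trend on genomic span (loess, span 0.3). Figures and tests of explanations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

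The tests were tried on simulated data for the diquat against control comparison, with counts drawn at 2.6 times counting error from the real means and depths and 200 genes changed. Over 18010 simulated genes, limma recovered 45 of 49 genes changed 4-fold, 36 of 50 changed 2-fold, 30 of 50 changed 1.5-fold and 17 of 49 changed 1.25-fold, and called 5 unchanged genes. Camera called 0 of 29 simulated sets of unchanged genes and called the set with 25 lowered genes. Simulated genes were drawn independently and few of them changed. The trial thus does not show how camera behaves on correlated lists or amid changes as wide as in these data.

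The design text speaks of 1 control and 1 treated sample and their duplicates, and no source says that libraries of a group came from separate batches of larvae. P-values then measure only the spread between these libraries, which may be technical. Replicates of a group differed by more than counting error, with a chi-square per gene between 2.35 and 2.62 at 20 to 10000 summed reads and of 5.08 (control) and 3.9 (diquat) above that. They were kept as separate libraries, as the labels list them. Whether read mates were counted separately, which alone would raise this value, was not settled, so the excess does not show that the libraries came from separate larvae.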

Results

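RNA from whole larvae of the Asian tiger mosquito, in the fourth instar, was sequenced after 72 h with or without diquat, a bipyridyl herbicide that cycles electrons to oxygen, at 1/5 of the LC50. Each group had 2 libraries. Control libraries held 34502559 and 39242657 counted reads and diquat libraries 45243090 and 48383964. The 4 libraries had reads for 22372 to 22669 of 25320 genes.

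The comparison asks which transcripts differ in larvae exposed to a sublethal dose of diquat. Transcripts of cuticle proteins, the structural proteins of the exoskeleton, fell widely: 141 of 174 tested genes fell, 96 of them at least 2-fold, and 7 rose. The lists of iron storage and NADPH supply, cytochrome P450s, immune genes and cytosolic ribosomal proteins rose by camera at a preset correlation of 0.01, a call that none of the 29 lists kept with an estimated correlation. The ferritin heavy chain (LOC109421124) rose by a log2 fold change of 1.15 ± 0.02 (SE, n = 2 per group), and the largest fall among the named genes was in a larval cuticle protein A2B-like gene (LOC109400301), from 563.7 ± 17.4 to 16.3 ± 1.06 normalized counts (SD, n = 2 per group). All 13 protein genes of the mitochondrial genome fell.

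Of 17992 genes tested, 8772 (48.8%) passed an adjusted p of 0.05 in limma, 4809 higher and 3963 lower with diquat. Most differences were small, with 65.7% of the called genes under 1.5-fold and 927 at 2-fold or more, of which 420 were higher and 507 lower. Both diquat libraries lay on the same side of both controls in 73.0% of tested genes, against 33.3% by chance. On the recovered reads edgeR called 8823 genes and DESeq2 6963. These p-values rest on 2 libraries per group that no source describes as separate batches of larvae.

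Among described genes, the largest rises included a pair named nose resistant to fluoxetine protein 6, LOC109427398 from 39.7 ± 14.9 to 1308 ± 13.2 normalized counts (SD, n = 2 per group; log2 fold change 5.06 ± 0.18, limma adjusted p = 1.74e-18) and LOC115256642 with a log2 fold change of 4.45. Both lie inside LOC109410169 in the AalbF5 annotation, and reads of the 3 genes were not separated here. A peritrophin-1 gene (LOC115257508), of a family of chitin-binding proteins that line the midgut, rose from 53.1 ± 9.07 to 1400 ± 47.8 normalized counts (SD, n = 2 per group; log2 fold change 4.71 ± 0.14, limma adjusted p = 3.1e-20). Another gene named peritrophin-1 (LOC115269993), more abundant in both groups, fell from 8921 ± 195 to 5584 ± 13.4 normalized counts (SD, n = 2 per group; log2 fold change -0.68 ± 0.03). Proteases among the 12 were a thymus-specific serine protease-like gene (LOC109414356, log2 fold change 4.91), serine protease persephone (LOC115256661, 4.22), serine protease K12H4.7 (LOC115258728, 3.47) and trypsin-1 (LOC109430115, 3.09). Persephone acts upstream of the Toll immune receptor in flies. Phenoloxidase-activating factor 2-like (LOC109416724), named for the melanization cascade, rose by 3.58 on the log2 scale. A trehalose transporter Tret1 gene (LOC109433130) rose by 4.67, from a low control mean of 5.83 normalized counts to 145.5. Of 34 tested genes of its product-name family, 7 rose and 6 fell. Rises of 3.76 and 3.34 were found in 2 synaptic vesicle glycoprotein 2B-like genes (LOC109424813 and LOC109414631). Vanin-like protein 1 (LOC109421937) was the most abundant of the 12, at 1628 ± 23.5 normalized counts in controls and 14416 ± 66.8 with diquat (SD, n = 2 per group; log2 fold change 3.15 ± 0.03, limma adjusted p = 1.96e-29). The undescribed genes LOC134287961 and LOC109430333 (inside LOC109430330) would have ranked among these 12, with log2 fold changes of 3.29 and 3.24.

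Of the 12 largest falls, 9 were in genes of the cuticle list. Larval cuticle protein A2B-like genes gave 5 of them, with log2 fold changes of -5.03 (LOC109400301), -3.34 (LOC109400303), -3.22 (LOC109425074), -3.13 (LOC134286750) and -2.67 (LOC134287877). The values were -3.94 (LOC109400285) and -2.73 (LOC134286741, inside LOC134287873) for cuticle protein 8-like genes, -2.76 for a pupal cuticle protein-like gene (LOC109420768) and -2.63 for adult cuticle protein 1 (LOC109421209). The other genes were cystathionine beta-synthase-like (LOC109427466), named for the enzyme that opens transsulfuration, from 2256 ± 11.1 to 138.9 ± 28.02 normalized counts (SD, n = 2 per group; log2 fold change -4.03 ± 0.11, limma adjusted p = 3.87e-21), histidine-rich glycoprotein-like (LOC134286749, -2.75) and calphotin-like (LOC109417942, -2.57).

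**Figure D1:**
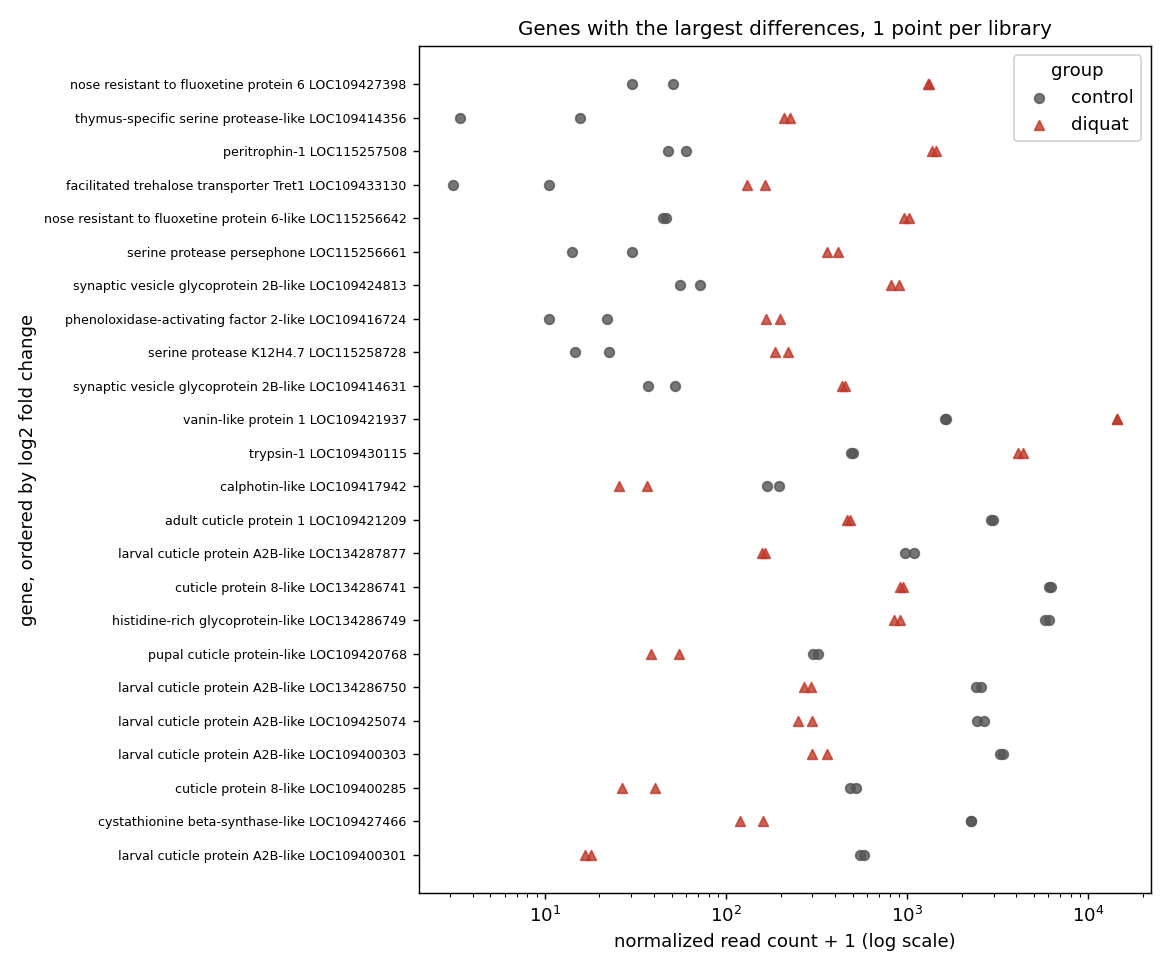
Normalized read counts plus 1 (log scale) of the 24 described genes with the largest rises and falls, 1 point per library, circles for control and triangles for diquat. In each gene both diquat libraries lie on the same side of both controls, and vanin-like protein 1 is at 14416 with diquat against 1628 in controls.

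The cuticle list had a median log2 fold change of -1.14 over its 174 tested genes (141 fell and 7 rose, and 141 and 7 adjusted over the list alone; camera adjusted p = 6.05e-38, and adjusted p = 0.0679 with an estimated correlation). Cuticle protein 8-like genes were abundant among them: LOC134287878 fell from 16816.5 to 3645 normalized counts and LOC134287876 from 12234 to 2080, with log2 fold changes of -2.21 and -2.56. Larval/pupal cuticle protein H1C (LOC109432235) fell by 1.37 on the log2 scale. The list's genes formed 53 runs of neighbours in the AalbF5 annotation, and reads shared among similar copies are not told apart in these values.

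Among 138 tested cytochrome P450s, enzymes that oxidise foreign compounds, 72 rose and 19 fell (73 and 20 adjusted over the list alone), 17 rose at least 2-fold and the median log2 fold change was 0.32 (camera adjusted p = 0.000133, and adjusted p = 0.221 with an estimated correlation). Without genes that overlap another, the P450 list had an adjusted p of 0.0704, its 10 alternatives ranged from 0.000214 to 0.221, and its median was 0.16 with the trend on genomic span removed. P450 6a14 (LOC109415288) rose by 1.65 ± 0.04 and 9b2 (LOC109429650) by 1.48 ± 0.06 (SE, n = 2 per group). UDP-glycosyltransferases, which conjugate sugars, had 16 rising and 4 falling of 33 (16 and 4 adjusted over the list alone; camera adjusted p = 0.0479, and adjusted p = 0.26 with an estimated correlation), among them LOC109622501 (inside LOC109408749) with a log2 fold change of 2.42. The call was lost in 9 of 10 alternatives (adjusted p from 0.0347 to 0.314). LOC109418392 of the same family fell by 0.30. With the span trend removed its log2 fold change was 0.06 and lost its call. Of 48 ABC transporters, 25 rose and 11 fell (26 and 11 adjusted over the list alone; camera adjusted p = 0.0369, and adjusted p = 0.246 with an estimated correlation), including multidrug resistance-associated protein 1 (LOC115262073) with a log2 fold change of 1.06, a call lost in 7 of 10 alternatives (adjusted p from 0.00243 to 0.246). The 36 glutathione S-transferases, with 17 higher and 6 lower (17 and 6 adjusted over the list alone), did not pass the set test (camera adjusted p = 0.171), although glutathione S-transferase 4-like (LOC109413318) rose by 2.40 on the log2 scale. Carboxyl and choline esterases went both ways, 11 higher and 12 lower of 37 (11 and 12 adjusted over the list alone; camera adjusted p = 0.542). Juvenile hormone esterase-like genes LOC109412453 and LOC109430352, named for the enzyme that breaks down that hormone, fell by 1.96 and 1.64 on the log2 scale.

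Genes of iron storage and NADPH supply rose in 11 and fell in 1 of 19 (11 and 1 adjusted over the list alone), with a median log2 fold change of 0.31 (camera adjusted p = 0.000113, and adjusted p = 0.246 with an estimated correlation). That median was 0.20 without diquat replicate 2 and 0.14 with the span trend removed. The ferritin light chain (LOC115254736) rose by 1.23 and transferrin (LOC109433636, inside LOC109408932), an iron carrier, by 0.86 on the log2 scale. Antioxidant enzymes rose in 18 and fell in 5 of 35 (19 and 5 adjusted over the list alone), none of them at 2-fold (camera adjusted p = 0.0281, and adjusted p = 0.246 with an estimated correlation). The antioxidant call was lost in 8 of 10 alternatives (adjusted p from 0.0225 to 0.254). Thioredoxin reductase 1 (LOC134285145) rose by 0.56 and thioredoxin-2 (LOC109409294) by 0.29. Heat shock proteins and chaperones rose in 40 and fell in 12 of 80 (41 and 12 adjusted over the list alone; camera adjusted p = 0.00234, and adjusted p = 0.246 with an estimated correlation), among them heat shock protein cognate 5 (LOC109401240) by 0.74. DnaJ protein homolog 1 (LOC115253617) was lower by -1.52, but a nested collagenase gene held 92.8% of its value. Unfolded protein and autophagy genes rose in 15 and fell in 3 of 26 (16 and 3 adjusted over the list alone; camera adjusted p = 0.0446, and adjusted p = 0.26 with an estimated correlation), and DNA repair and apoptosis genes in 30 and 6 of 63 (32 and 7 adjusted over the list alone; camera adjusted p = 0.0174, and adjusted p = 0.246 with an estimated correlation), the latter including ribosome biogenesis protein NOP53 (LOC109431436) at 0.83, the helicase subunit XPB (LOC109401156, inside LOC109401159) at 0.74 and death-associated inhibitor of apoptosis 1 (LOC109411467), a caspase inhibitor, at 0.47. NOP53 entered the DNA repair list because its name holds the letters of that list's p53 pattern, while its product name describes ribosome biogenesis. The calls of the 2 lists were lost in 8 of 10 alternatives for unfolded protein (adjusted p from 0.0416 to 0.361) and 7 of 10 for DNA repair (0.0108 to 0.254). Proteasome genes gave 8 higher and 6 lower of 38 (8 and 6 adjusted over the list alone; camera adjusted p = 0.724).

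Immune recognition and effector genes rose in 88 and fell in 22 of 168 (89 and 22 adjusted over the list alone; median log2 fold change 0.32, camera adjusted p = 0.000221, and adjusted p = 0.224 with an estimated correlation). The immune call was lost in 2 of 10 alternatives, the estimated correlation and the replicate block (camera adjusted p = 0.0564). Melanization protease 1 (LOC109424794) rose by 0.86 and phenoloxidase-activating factor 1-like (LOC109424806) by 0.78. Peptidoglycan-recognition protein SC2-like (LOC109425525), a binder of bacterial cell wall, fell by 0.77. Haemocyte and matrix markers had 5 rising and 15 falling of 34 (5 and 15 adjusted over the list alone; camera adjusted p = 0.0206, and adjusted p = 0.329 with an estimated correlation). The haemocyte call was lost in 4 of 10 alternatives, among them no overlapping genes (0.085) and the span trend removed (0.229). Papilin (LOC109411053), the member of smallest p, was at -0.71, with 28.96% of its value in a nested larval cuticle protein gene. Protein croquemort (LOC109424474, inside LOC134288002), the next by p, rose by 0.85.

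Cytosolic ribosomal protein genes rose in 83 and fell in 1 of 89 (84 and 1 adjusted over the list alone; median log2 fold change 0.35, camera adjusted p = 1.23e-44, and adjusted p = 0.246 with an estimated correlation). The ribosomal median was 0.17 under quantile normalization. Large subunit protein uL10 (LOC109401487) rose by 0.62. Glycolysis and citrate cycle genes rose in 22 and fell in 7 of 32 (22 and 7 adjusted over the list alone; camera adjusted p = 0.00125, and adjusted p = 0.246 with an estimated correlation), with cytoplasmic aconitate hydratase (LOC109409733) at 0.62. Malpighian tubule and ion transport genes, the proton and sodium pumps of the excretory system among them, rose in 32 and fell in 16 of 60 (33 and 16 adjusted over the list alone; camera adjusted p = 0.00507, and adjusted p = 0.246 with an estimated correlation), such as V-type proton ATPase subunit B (LOC109430213) at 0.48. Hexamerins and storage proteins, amino acid reserves of the larva, gave 3 rising and 4 falling of 14 (3 and 4 adjusted over the list alone; camera adjusted p = 0.0469, and adjusted p = 0.457 with an estimated correlation). The hexamerin call was lost in 5 of 10 alternatives, among them a mean of at least 50 (0.0527) and no overlapping genes (0.0632). The hexamerin median of -0.05 turned to 0.00 without control replicate 2. Hexamerin-1.1 genes LOC109419367 and LOC109398558 (the latter inside LOC109398559) fell by 0.54 and 0.76. Quantile normalization ended the calls of the glycolysis and citrate cycle list (camera adjusted p = 0.0888) and of the Malpighian tubule list (0.0517).

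Neuronal and synaptic genes fell in 64 and rose in 9 of 106 (66 and 9 adjusted over the list alone; median log2 fold change -0.36, camera adjusted p = 3.21e-08, and adjusted p = 0.198 with an estimated correlation). Neuropeptide SIFamide receptor (LOC109402751) was lower by -0.62, with 45.8% of its value in a nested gene, and a potassium voltage-gated channel gene (LOC109622630) fell by 0.56 with 0.618% of its value in a nested gene. Fold changes differed with gene length: of 10 equal groups of protein-coding genes by genomic span (AalbF5), the longest had a median log2 fold change of -0.32 and the third shortest 0.29. After removal of that trend the neuronal median was -0.13. Long noncoding RNAs fell more often than they rose, with 83 higher and 376 lower of 1771 and a median of -0.28, as did pseudogenes with 19 higher and 56 lower of 240 and a median of -0.33.

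**Figure D2:**
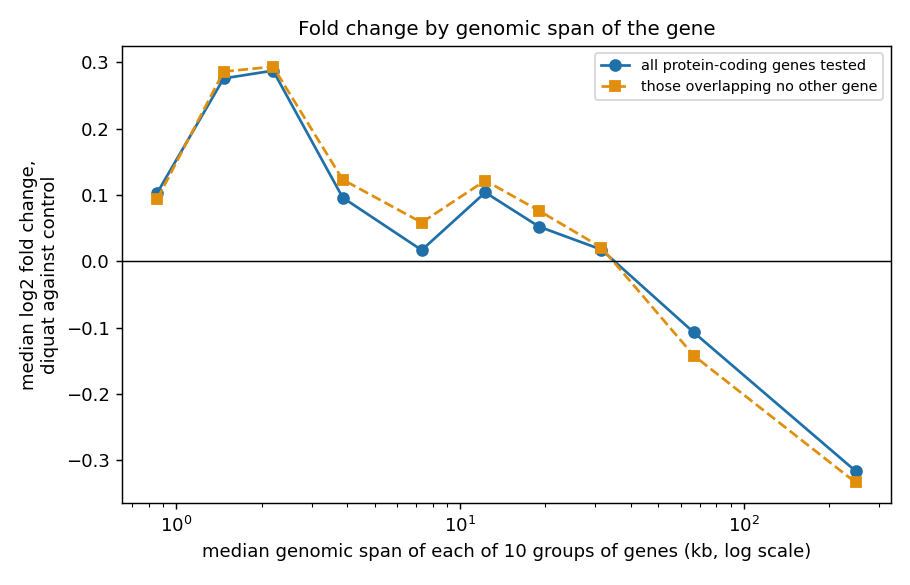
Median log2 fold change of diquat against control (y axis) over 10 equal groups of tested protein-coding genes by genomic span in kb (x axis, log scale), for all such genes and for those overlapping no other gene. The longest group lies at -0.32 and, without overlapping genes, at -0.33.

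Lists that did not pass the set test held changed genes in both directions. Digestive proteases had 52 higher and 30 lower of 125 (53 and 31 adjusted over the list alone; camera adjusted p = 0.288), with zinc carboxypeptidase-like LOC109420740 at -2.31. Carbohydrate and lipid digestion had 19 and 17 of 55 (19 and 17 adjusted over the list alone; camera adjusted p = 0.753), where pancreatic lipase-related protein 2 (LOC109428377) stood at 2.74 and lipase member H-like (LOC109426866) at -2.06. Chitin and peritrophic matrix genes had 17 and 11 of 41 (17 and 11 adjusted over the list alone; camera adjusted p = 0.414). Ecdysone and juvenile hormone genes had 9 and 12 of 33 (9 and 13 adjusted over the list alone; camera adjusted p = 0.268), with zinc finger protein on ecdysone puffs (LOC109416338) at 0.38, the ecdysone receptor (LOC109414899) at -0.51, nuclear receptor HR3 (LOC109417772) at -0.46 and FTZ-F1 (LOC109404941) at -0.55, the last 3 of them nuclear receptors of the moulting hormone response. Fatty acid genes had 37 and 24 of 90 (38 and 25 adjusted over the list alone; camera adjusted p = 0.184), with acyl-CoA Delta-9 desaturase (LOC109412434) at 0.75. DNA replication genes had 9 and 12 of 47 (9 and 12 adjusted over the list alone; camera adjusted p = 0.455), muscle genes 21 and 20 of 60 (22 and 20 adjusted over the list alone, 1 higher and 6 lower at 2-fold; camera adjusted p = 0.492), photoreceptor and chemosensory genes 26 and 27 of 122 (25 and 27 adjusted over the list alone; camera adjusted p = 0.434), and germline and sperm genes 17 and 13 of 80 (16 and 12 adjusted over the list alone; camera adjusted p = 0.724).

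Oxidative phosphorylation genes had 32 higher and 25 lower of 88 (32 and 27 adjusted over the list alone; camera adjusted p = 0.684). The list passed as lower under quantile normalization (adjusted p = 0.0324), under the replicate block (0.033), without control replicate 2 (0.025) and with the span trend removed (0.00564), over a range of 0.00564 to 0.846. The oxidative phosphorylation list includes genes of the mitochondrial genome. Its 4 members of smallest p were NADH-ubiquinone oxidoreductase chain 1-like (LOC134284466, -0.97), COX3 (-0.64), COX1 (-0.31) and chain 5-like (LOC134284215, inside LOC109410943, -0.80). The 13 protein genes of the mitochondrial genome, a list added after the data were seen, all fell. Their median log2 fold change was -0.91, with a range from CYTB at -0.25 to ND2 at -1.73. ND2 fell from 13484 ± 432.5 to 4058 ± 11.3 normalized counts (SD, n = 2 per group). The mitochondrial rRNA KEG16_r02 fell by 1.18 on the log2 scale and the other, KEG16_r01, by 0.19, and reads of mitochondrial genes made up 4.88% and 4.87% of control libraries against 2.49% and 2.45% with diquat. Most of that difference lay in KEG16_r02, at 3.79% and 3.76% against 1.68% and 1.65%, while the 13 protein genes together held 1.06% and 1.08% against 0.795% and 0.79%. The most counted gene of every library, integrin alpha-PS2 (LOC109428417), held 1.08 to 1.1 times the value of KEG16_r02. It held 4.17% and 4.15% of control reads and 1.81% and 1.78% of diquat reads. Because it followed KEG16_r02 so closely, its fall cannot be told apart from that of mitochondrial rRNA reads counted at this gene. The mitochondrial shares above leave out any such reads.

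**Figure D3:**
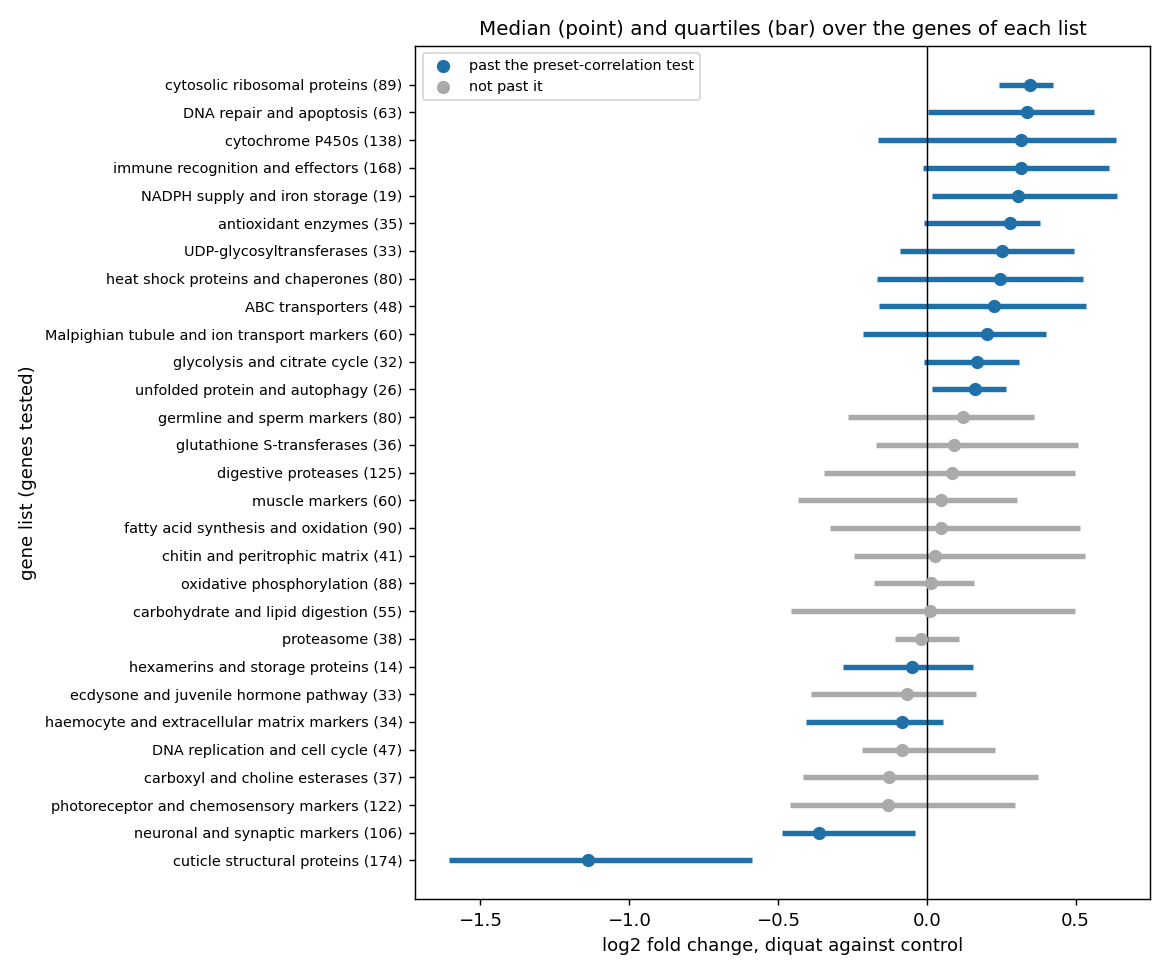
Median (point) and quartiles (bar) of log2 fold changes, diquat against control (x axis), over the tested genes of each of 29 lists (y axis, number tested in brackets), blue where camera at the preset correlation passed and grey where it did not. Cuticle genes lie lowest at -1.14 and, as deposited, cytosolic ribosomal proteins highest at 0.35, a place taken by immune genes at 0.32 under quantile normalization; none of the lists passed with an estimated correlation.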

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

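The settings without overlapping genes, with nuclear protein-coding genes only and with the span trend removed were chosen after the data were seen; the others were planned. The count of changed genes (8772) ranged from 5999 with a constant variance prior to 9056 under the replicate block, apart from the settings that narrow the genes. A 2-fold minimum left 927 genes, 420 higher and 507 lower. Among genes without overlap, a setting that also left out 742 genes placed on no chromosome, 4962 of 10471 changed, 3027 higher and 1935 lower; fewer genes were tested, and the cause of the higher share of rises (61.0% against 54.8%) was not tested. Leaving out 1 library gave 6833 to 8339 changed genes, 3748 to 4661 higher and 3085 to 3678 lower. In those fits the lone library of a group is assumed to vary like the other group. Without control replicate 1 the set tests lost were UDP-glycosyltransferases (adjusted p = 0.12), ABC transporters (0.0837), antioxidant enzymes (0.231), DNA repair (0.232), unfolded protein (0.295) and haemocyte markers (0.0524). Without control replicate 2 the first 5 of these were lost again, at 0.0795, 0.0795, 0.237, 0.237 and 0.276. Calls gained were muscle (0.0342) without control replicate 1, and muscle (0.0491) and oxidative phosphorylation, lower (0.025), without control replicate 2. With the span trend removed the proteasome (0.00126) and oxidative phosphorylation (0.00564) passed as lower. Without diquat replicate 1 UDP-glycosyltransferases and hexamerins (both 0.0837) were lost, and without diquat replicate 2 hexamerins (0.0619). Quantile normalization ended, among others, glycolysis and citrate cycle (0.0888) and Malpighian tubule genes (0.0517). With the span trend removed 7783 genes changed, 113 of the shared calls with the opposite sign. Of 140 named genes, 129 kept their direction and call in every alternative that tested them and 10 lost the call in 1 or more. These counts leave out the 2-fold minimum, which named genes under 2-fold do not pass. Apart from the estimated correlation, 11 of the called lists lost their call in 1 or more alternatives. Of 29 lists, 16 passed, against 10 at a mean of at least 50, 8 without overlapping genes and 0 with an estimated correlation. Fry passed 25 for a shared direction and 29 for change in either direction. The estimated correlation was below the preset 0.01 in the cuticle (0.000561), neuronal (-0.000116) and P450 (-0.00307) lists. It was above that in others, such as ribosomal proteins (0.446). A higher correlation thus does not account for the lost calls of the cuticle, neuronal and P450 lists. Camera with an estimated correlation also takes its degrees of freedom from the few libraries, where the preset form takes them from the genes. A lost call there does not by itself show correlated genes. Causes of the lost calls were not tested further. The log2 fold change of LOC115253756 (activating transcription factor of chaperone) reversed to -0.0607 under quantile normalization, and the log2 fold change of LOC109418392 (UDP-glucosyltransferase 2) to 0.0639 with the span trend removed; the cause was not tested. The replicate numbers are shared only as numbers: deviations of same-numbered libraries correlated at 0.0118 across genes, and the replicate block ended the calls of 6 lists (immune genes at 0.0564, ABC transporters at 0.113, UDP-glycosyltransferases at 0.163, antioxidant enzymes and DNA repair at 0.254, unfolded protein at 0.277) and passed oxidative phosphorylation (0.033, lower) and muscle (0.0151, higher by camera, though the list's mean log2 fold change was -0.11 and fry pointed lower). Depth limits the low genes: replicates of a group differed by a median of 0.423 and 0.432 on the log2 scale at 20 to 100 summed reads, against 0.0603 and 0.0601 at 1000 to 10000.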

Other observations

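The tests in this part on uniform mitochondrial change and on gene span as the whole cause of the neuronal fall, and the search over product-name families, were chosen after the results were seen; the bounds of the other tests were set before. Among 216 families of product names, translation initiation and related factors rose in 37 and fell in 3 of 47 genes (median log2 fold change 0.42), T-complex chaperonin subunits rose in 10 of 11 (0.63), V-type proton ATPase subunits in 19 of 21 (0.38, and 0.25 under quantile normalization), mitochondrial import proteins in 15 of 22 (0.44) and aminopeptidase N genes in 19 of 27 (0.39). Mucin genes fell in 34 and rose in 11 of 63 (-0.32), and potassium voltage-gated channel genes fell in 11 of 11 (-0.56). Each passed camera at the preset correlation, and each had an adjusted p of 0.522 with an estimated correlation.

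Cuticle genes fell across the list, and 2 technical explanations were tested. Genes outside the list matched on genomic span and level had a median log2 fold change of 0.126, against -1.14 for the list, which argues against a bias against short genes. Counting each run of neighbouring cuticle genes once, 47 of 53 runs (88.7%) had a negative median, which argues against a few groups of neighbouring copies as the source. Runs were set by gene order and not by sequence. Similar copies in different runs may still share reads, which this test cannot exclude. An effect of diquat exposure itself, the difference the design names, stays open and untested beyond these values.

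Mitochondrial transcripts fell with diquat. The log2 fold changes of the 13 messages ranged over 49.5 times their median standard error, which argues against a uniform fall of their counted values. Some similar genes annotated outside the mitochondrial genome held more reads. NADH-ubiquinone oxidoreductase chain 1-like (LOC134284466) averaged 261902 normalized counts in controls against 6730 for ND1. Chain 5-like (LOC134284215) averaged 16519 against 1138 for ND5. How reads were divided among such copies is not given, so a uniform fall per larva is not settled. The histone genes entered in the next test were chosen, leaving out variants and modifying factors, after a first look at their unfiltered median. Less carry-over of RNA without poly(A) tails may contribute, but it was tested on nuclear RNAs, which need not behave like the 13 messages. The 56 histone and snRNA genes had a median of -0.462, between the bounds of -0.5 and -0.25 set beforehand. The 51 histone genes alone were at -0.396 and the 5 snRNA genes, 0 of them called, at -0.638. Such carry-over cannot be told apart from a biological change. The kit's selection step is not given in the sources used here.

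Neuronal genes fell, and 2 technical explanations were tested. Fewer reads from long gene bodies may account for much of the fall, since genes matched on span and level had a median of -0.256 against -0.362 for the list, past the bound of -0.25 set beforehand, with 95% of draws between -0.317 and -0.199. Whether fewer reads from long gene bodies are the whole cause was not settled. Of 1000 draws of matched genes, 0 had a median as low as the list. These draws varied only the matched genes and left out the uncertainty of the list's own median. With the span trend removed the list still passed camera as lower (adjusted p = 0.00564). The 56 members without overlap, at -0.303, lay within the range of 95% of draws, which were matched to the whole list. Reads of overlapping genes are argued against, because the 56 list members without overlap had a median of -0.303. A neuronal effect of diquat stays open and untested beyond these values.

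Replicates of a group differed by a nearly constant multiple of counting error at 20 to 10000 summed reads (chi-square per gene 2.35 to 2.62) and by more above that (5.08 in controls and 3.9 with diquat), and 1 candidate explanation, that both mates of a read pair were counted as separate reads, was tested with bounds set beforehand. Genes with 2 reads were 1.37 times as frequent as the mean of genes with 1 and 3 reads (median of 4 libraries, range 1.3 to 1.43), between the bound of 1.5 for that explanation and 1.2 against it, so the test was inconclusive. Genes with 4 reads, looked at afterwards, were 1.27 to 1.41 times as frequent as the mean of those with 3 and 5 reads.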
